A study of Rattus norvegicus with 8 samples.

How the data were processed

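Primary vascular smooth muscle cells from the thoracic aorta of Sprague-Dawley rats were compared without stimulation and after 3 h with 0.1 uM angiotensin II (AngII), the peptide hormone that constricts vessels and stimulates smooth muscle growth. The series holds 8 samples, of which 6 libraries with files were analysed: RNA-seq, H3K4me3 ChIP-seq and H3K36me3 ChIP-seq, with 1 library per condition. The 2 input libraries were not analysed here. H3K4me3 is a histone mark of promoters and H3K36me3 a mark of transcribed gene bodies. Overnight serum starvation is stated for the AngII-treated samples only, per the labels, and whether the control cells were starved is not stated there, so starvation and AngII could not be separated from the labels alone. Samples were assigned to groups by their titles.

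RNA abundance is in FPKM, deposited by the authors with lower and upper confidence bounds for each locus. TopHat, Cufflinks and Cuffdiff, and the rat assembly rn4, are named in the submitters' processing notes without versions. The RNA was depleted of ribosomal RNA, per the labels. The RNA tables of the control and AngII samples were identical byte for byte, and this table holds both conditions. It lists 30937 loci, and 15 had no usable estimate in at least 1 library. The FPKM bounds deposited by the authors lie 2 SD either side of each estimate; at FPKM of 10 or more the implied relative SD had a median of 21.1% in both libraries, so bounds separate only from about 2.46-fold. They are model errors and hold no replicate variation. Sequencing depth is not given in the sources used here. The bounds of weakly expressed loci imply whole fragment numbers for 81.1% of 2183 control loci and 81.8% of 3767 AngII loci, within 0.03 of a whole number. Over 527 loci the FPKM worth of 1 fragment was 1.01 times as large in control as in AngII (interquartile range 1.01 to 1.02), so the normalising depths were close.

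The ChIP-seq files list regions with a score that the authors deposited for each region. Bowtie is named in the submitters' processing notes; the region caller is not given in the sources used here. Regions are whole multiples of a bin that differs between lists: 153 bp for control H3K4me3, 160 bp for AngII H3K4me3, 589 bp for control H3K36me3 and 548 bp for AngII H3K36me3. The score is the authors' own value and was used only to rank and filter regions within a list.

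Accessions were paired with gene symbols through a RefSeq table of the assembly GRCr8, used for names only. Of 20869 loci with an accession, 16252 (77.9%) matched and 16025 matched exactly 1 symbol. Genes without a matched locus, Acta2 among them, were not analysed here. Coordinates are those of the files. Strand is not given for the RNA loci, and 6014 loci (19.4%) share their coordinates with another locus because a Cuffdiff locus can span several neighbouring genes.

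The log2 ratio is log2((AngII FPKM + 1)/(control FPKM + 1)), which understates differences of weakly expressed loci. A locus was expressed at FPKM of 1 or more in at least 1 library. With 1 library per condition there was no test and no p-value, and the difference between conditions has no replicate check. Loci were counted by a rule of size, a 2-fold ratio on the pseudocount scale, and the number whose bounds do not overlap is given beside it. For gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean FPKM in 10 bins, as a description of these libraries. The locus with the highest mean FPKM stood for each symbol.

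Regions were compared by overlap of at least 1 bp, with the same overlap after 20 random shifts of the other list as background, and by the Jaccard index of covered base pairs, whose spread was taken from a binomial interval with regions as units. A gene had H3K4me3 when a region lay within 1 kb of its locus and H3K36me3 when a region touched the locus. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Genes higher or lower than 2-fold with bounds apart were compared for the percent of the locus under H3K36me3, using loci with 1 symbol and coordinates of their own. Random sets were matched on mean FPKM, on control cover, or on control cover, control FPKM and locus length together, the last chosen after seeing the data.

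The choice of design, alternatives and 17 gene lists was made before the data were examined; 5 further lists were added after seeing the data. The text names the 12 genes with the largest increase and the 12 with the largest decrease among expressed genes with bounds apart, leaving out small RNAs. It also names up to 4 genes per list with the largest absolute log2 ratio, a fixed set of reference genes, up to 5 unnamed loci with both marks that were higher and 3 that were lower, and the 3 regions with the highest score per list. Some genes these rules select are not reported here. Other names are said to be chosen after their values were seen. The alternatives varied the pseudocount, FPKM minimum, scaling, threshold, bounds, overlap rule, score filter and window.

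Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data for this comparison with the means and bounds of 16654 loci. Of 100 loci changed by a log2 of 2, 66 were recovered with the correct sign by the rule of size with bounds apart, as were 86 of 100 changed by a log2 of 3. Of the unchanged loci, 333 (2.02%) passed the rule of size alone and 24 also had bounds apart. The simulated noise came from the same errors that set the bounds and held no variation between cultures. These numbers are therefore not rates of false calls in the real libraries. A list of 15 genes shifted by a log2 of 1 stood at percentile 100, and 2 of 100 unshifted lists of 15 lay outside the 2.5th to 97.5th percentile. No per-sample column was left unused.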

Results

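Gene expression and 2 histone marks were measured in rat aortic smooth muscle cells in the unstimulated state and 3 h after 0.1 uM AngII. The series title and design concern long non-coding RNAs regulated by AngII. There was 1 library per condition and assay, so no difference below has a replicate check. Of 30922 loci with a usable estimate, 16654 were expressed.

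AngII-treated cells had much higher RNA levels of early response genes and of the prostaglandin synthase Ptgs2. Ptgs2 stood at 3.89 FPKM in control (bounds 1.95 to 5.84) and 86.1 FPKM after AngII (50.1 to 122). Genes with the largest increase included Fosl1 (4.74), Arc (4.60), Egr1 (4.52), Dusp5 (4.33), Nr4a3 (4.22), Ptgs2 (4.15), Nr4a1 (4.10), C9h6orf141 (4.10), Rgs16 (4.07), Hivep3 (3.86) and Noct (3.80). The 12 with the largest decrease were Fgf16 (-2.96), Adamts15 (-2.57), Otub2 (-2.23), Mybphl (-2.15), Klf15 (-2.10), Kctd7 (-2.09), Gdf6 (-2.06), P2ry6 (-2.02), Fzd1 (-1.99), Tbx18 (-1.91), Tmem218 (-1.82) and Hs6st1 (-1.79). Gdf6, a bone morphogenetic protein family ligand, stood at 153 FPKM in control and 36.1 FPKM after AngII. Fgf16, a fibroblast growth factor on chromosome X (93870483 to 93880067), stood at 35.9 and 3.75 FPKM. Fosl1 (chromosome 1, 208090611 to 208099118), an AP-1 subunit, stood at 0.685 and 43.9 FPKM. The symbols C9h6orf141 and Hs6st1 matched 2 loci each, and the listed coordinates of Egr1, Nr4a1, Rgs16, Klf15 and Kctd7 span several loci, so these are uncertain.

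**Figure D1:**
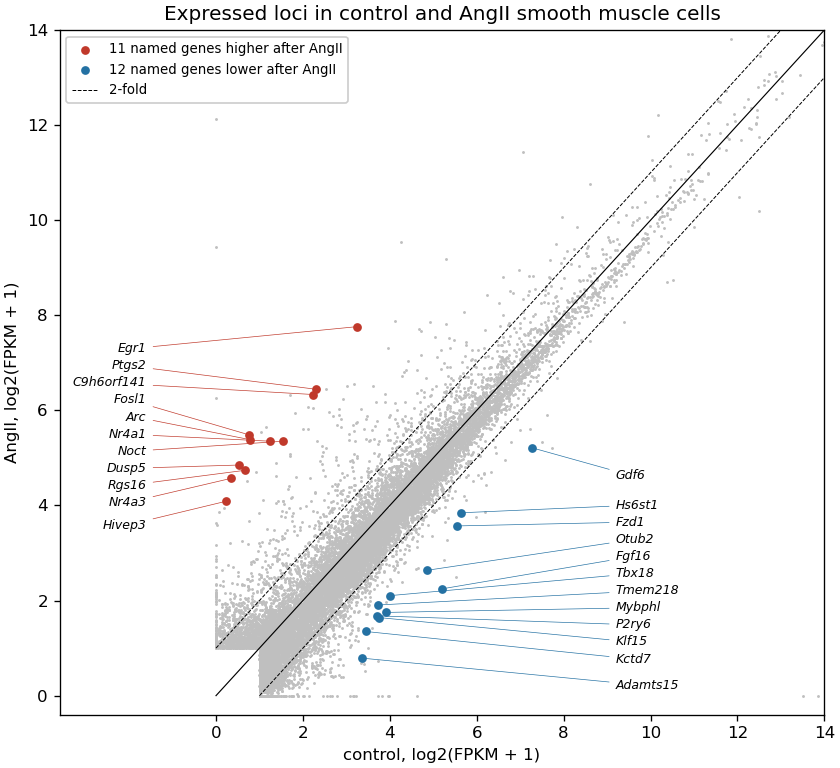
Control FPKM (x axis) against AngII FPKM (y axis) of the expressed loci, both as log2(FPKM + 1), with named genes higher (red) and lower (blue) after AngII and dashed lines at a 2-fold ratio; 49 loci lie outside the axes. Ptgs2 reaches 86.1 FPKM after AngII, and more grey points lie below than above the diagonal.

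Among all expressed loci, 772 were at least 2-fold higher after AngII (506 with bounds apart) and 923 at least 2-fold lower (512 with bounds apart). Among loci with exactly 1 symbol, 337 were higher and 264 lower, of which 234 and 139 had bounds apart. The median expressed locus had a log2 ratio of -0.24 (interquartile range -0.54 to 0.11), and 68.6% of loci were below 0. After scaling AngII values by 1.21 to centre this shift, 1201 loci were higher and 602 lower, so the higher loci made up 66.6% of the calls against 45.5% before; with a pseudocount of 5 they made up 72.1% and with 0.1 they made up 32.3%. The values that follow are as deposited, beside a median of -0.22 over 8354 expressed symbols.

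Immediate early genes, transcription factors and feedback regulators induced within minutes to hours of stimulation, were the list with the highest median. Of 26 expressed members 18 were at least 2-fold higher (17 with bounds apart) and 0 lower, with a median log2 ratio of 1.65 at percentile 100 of random lists. Fosl1, Egr1, Dusp5 and Nr4a3 led the list. Fos itself stood at 1.24 FPKM in control and 10.3 FPKM after AngII, a log2 ratio of 2.34, while Myc (-0.12) and Dusp1 (0.09), named after their values were seen, were near 0.

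Growth factor genes had a median log2 ratio of 1.02 (percentile 100), and 8 of 15 were at least 2-fold higher, 5 of them with bounds apart. Pdgfb, a smooth muscle mitogen, stood at 2.28 FPKM in control and 32.8 FPKM after AngII (3.37), followed by Fgf2 (2.66), the EGF receptor ligand Hbegf (2.52) and the activin subunit Inhba (2.18). Inflammatory genes had a median of 0.52 (percentile 100), with 5 of 12 at least 2-fold higher: Ptgs2, Lif (1.99), the chemokine Ccl2 (1.92), Cxcl1 (1.66) and Ccl7 (1.55), the last named after its value was seen. Extracellular matrix genes had a median of 0.19 (percentile 98.8), with 2 of 14 higher and 1 lower (4 and 0 under centring); without the FPKM minimum the median was 0.02 (percentile 92.5). Bounds were apart for 1 of the 2 higher members. Adamts1 (1.32) was past 2-fold and Timp1 (0.93) was not, both with overlapping bounds. Elastin (Eln) was lower at -1.01, and its listed locus and another share the symbol. Of the 14 members 8 lay above 0 and 6 below, as deposited and under centring. Among those below 0 were the collagens Col3a1 (-0.61), Col1a2 (-0.36), Col1a1 (-0.35) and Col4a1 (-0.35), named after their values were seen. The bounds of these collagens overlapped, and the symbols Col3a1 and Col1a1 matched 2 loci each.

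Genes of angiotensin signalling and G-protein regulators moved in opposite directions. Agtr1a, the AngII type 1 receptor, stood at 99.2 FPKM in control and 30.1 FPKM after AngII, a log2 ratio of -1.69 (chromosome 17, 40629317 to 40684982). Rgs4, which dampens G-protein signalling and was named after its value was seen, was also lower (-1.55). Rgs16 and Rgs2 (2.90) of the same protein family were higher. Of 12 expressed members 5 were at least 2-fold higher and 2 lower, with a median of 0.24 (percentile 99.7), and 0.06 over 17 members without the FPKM minimum. Agtr1b stood at 0.0670 and 0.113 FPKM, below the expression minimum.

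Cholesterol synthesis genes had a median log2 ratio of 0.56 (percentile 100). The sterol oxidase Msmo1 (2.18) and the isoprenoid isomerase Idi1 (1.28) were among the 4 of 14 at least 2-fold higher. Unfolded protein and amino acid stress genes had a median of 0.59 (percentile 99.99), with 4 of 14 at least 2-fold higher: Chac1 (2.08), the chaperone Hspa5 (1.54), Ppp1r15a (1.36) and Creld2 (24.4 FPKM in control and 53.3 FPKM after AngII). Bounds were apart for 3 of the cholesterol genes and 2 of the stress genes. Heat shock genes had a median of 0.28 (percentile 98.2), and 1 of 8, Cryab (1.02), was 2-fold higher without bounds apart; Bag3 (0.80), Hspb1 (0.58) and Hsph1 (0.32) followed.

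Cell cycle genes were lower after AngII in all 14 expressed members, with a median log2 ratio of -0.44 (percentile 1.57) and 0 members past 2-fold. The kinase inhibitors Cdkn1b (-0.95) and Cdkn2c (-0.73), the spindle kinase Bub1 (-0.65) and Mcm6 (-0.63) had the largest differences. Scaled to centre the median locus, the list median was -0.17 and 2 members lay above 0; with a pseudocount of 0.1 the percentile was 2.6.

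Smooth muscle contractile genes had 0 of 16 members past 2-fold and a median of -0.09 (percentile 68.3) as deposited. Under centring the median was 0.18, 14 of 16 lay above 0 and 3 were past 2-fold (Myocd, Vcl and Smtn); scaled to the upper quartile 2 were. Myocd (0.97), Vcl (0.97), Smtn (0.74) and Cnn1 (0.46) were the members furthest from 0. Tagln stood at 5103 FPKM in control and 5244 FPKM after AngII (0.04). Myh11 stood at 96.5 and 84.7 FPKM (-0.19, and above 0 under centring). Housekeeping genes had a median of -0.18 (percentile 36.7) and 0 of 13 past 2-fold, which was 0.09 under centring. Gapdh was at 0.06 and Actb at 0.14, both above 0 under each scaling, while Sdha (-0.58), Ywhaz (0.38) and Rplp0 (-0.35) lay further from 0.

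Markers of other cell types were low or little different. None of 8 endothelial and none of 7 adipocyte markers with a locus was expressed, with highest values of 0.668 and 0.181 FPKM. Of 11 leukocyte markers 2 were expressed, Cd14 (0.27) and Cd74 (-0.11). Of 8 Schwann cell and neuron markers 2 were expressed, among them Tubb3 (0.82). Adventitial fibroblast markers had 7 expressed members with a median of -0.36 (percentile 15.7), led by Pi16 (-0.53), Dpep1 (-0.42), Pdgfra (-0.41) and Mfap5 (-0.36). Not all of this list was low. Lum stood at 140 FPKM in control and 111 FPKM after AngII, Gsn at 123 and 125 and Igfbp6 at 29.1 and 23.4. These members were named after their values were seen. Of the named long non-coding RNAs only 3 had a matched locus and the others were not analysed here. Snhg4 (0.93), Gas5 (-0.60) and Rpph1 (-0.25, at an interval shared by 16 loci) were expressed, all with overlapping bounds and with a median of -0.25 (percentile 39.5) that was 0.02 under centring.

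**Figure D2:**
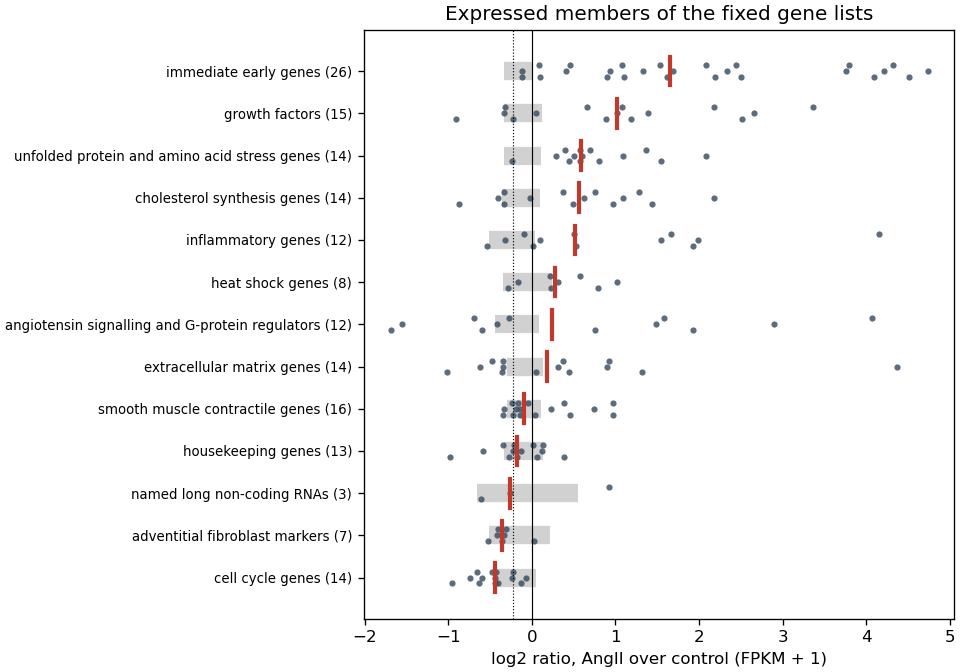
Log2 ratio of AngII over control, on FPKM + 1 (x axis), for each expressed member (dots) of the fixed gene lists with at least 3 expressed members, whose number is in parentheses; red bars are list medians, grey bars span the central 95% of random-list medians, and the dotted line is the median of all expressed symbols, -0.22. The median of the immediate early genes is 1.65 and that of the cell cycle genes is -0.44.

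H3K4me3 covered similar parts of the genome in both conditions. The control library had 28168 regions over 81.5 Mb and the AngII library 27801 over 82.6 Mb. Of the control regions 87.8% (95% interval 87.4 to 88.2) overlapped an AngII region, against 6.25% after shifting, and of the AngII regions 88.6% (88.2 to 89.0) overlapped a control region. The Jaccard index was 0.713, against 0.0174 after shifting. Regions without a partner were narrow, with a median of 765 bp in control against 2142 bp for the others, and overlap went from 66.5% in the lowest score quartile of control regions to 99.3% in the highest. The control regions with the highest score lay on chromosome 9 (16890978 to 16891130, within a listed locus of Crisp3 and Pgk2), chromosome 1 (9156535 to 9156687) and chromosome 4 (66164450 to 66164602). Those of AngII lay on chromosome X (29823568 to 29823727), chromosome 14 (103999874 to 104000193) and chromosome 3 (148551288 to 148551447, at Ctnnbl1). These were 153 to 320 bp wide, and all but the chromosome 1 region were overlapped in the other list.

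H3K36me3 covered 578 Mb in 17425 control regions and 588 Mb in 16578 AngII regions. Of the control regions 77.8% (77.1 to 78.4) overlapped an AngII region and of the AngII regions 77.7% (77.1 to 78.3) overlapped a control region, against 33.5% and 34.7% after shifting. The Jaccard index was 0.776, against 0.128 after shifting. The control regions with the highest score lay on chromosome 6 (91379875 to 91381052), chromosome 14 (28434226 to 28434814, at Adgrl3) and chromosome 15 (26730737 to 26731325, within a listed locus of several genes including Apex1). Those of AngII lay on chromosome 13 (30743956 to 30744503, the only one of these 6 without overlap in the other list), chromosome 6 (22163035 to 22164130, at Capn13) and chromosome 14 (28433994 to 28434541, at Adgrl3).

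Expressed genes carried both marks far more often than silent genes. Among loci with an accession and FPKM of 1 or more in control, 90.5% (90.0 to 91.0) had H3K4me3 and 93.4% (92.9 to 93.8) had H3K36me3. At FPKM under 0.1 the shares were 49.7% (48.4 to 51.0) and 37.0% (35.7 to 38.2). After AngII the shares were 91.8% and 94.9% at FPKM of 1 or more and 48.5% and 41.0% at FPKM under 0.1. Over loci with coordinates of their own, 33.7% of silent genes had H3K4me3 and 16.9% had H3K36me3 in control.

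**Figure D3:**
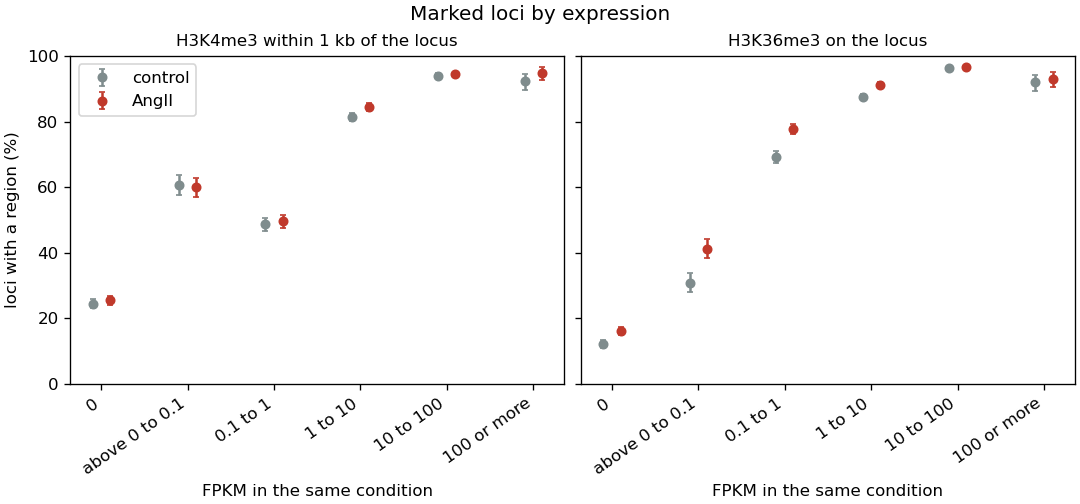
Share of loci with H3K4me3 (left) and H3K36me3 (right) in percent (y axis) by FPKM class in the same condition (x axis), for loci with an accession and coordinates of their own; points are control (grey) and AngII (red) and bars are exact 95% intervals for counting error. In control, H3K36me3 goes from 12.1% of loci at FPKM 0 to 96.3% at FPKM 10 to 100.

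Genes higher after AngII had more of their locus under H3K36me3 after treatment, while H3K4me3 in control was about as frequent at them as at other expressed genes. Among 181 genes at least 2-fold higher with bounds apart, 170 (93.9%, 89.4 to 96.9) had H3K4me3 in control and 172 after AngII; in control the share was 94.6% of the lower and 95.2% of the other expressed genes. Mean H3K36me3 cover was 64.1% of the locus in control and 84.5% after AngII, a difference of 20.4 points. The median cover of the 181 genes was 90.5% in control and 100% after AngII. Fos, Arc, Nr4a3 and Pdgfb, chosen after their values were seen, had H3K4me3 in both conditions. Their H3K36me3 cover was 0% in control and 100% after AngII. Ptgs2 and Inhba stood at 100% in both conditions, and Cxcl1 and Ccl2 at 0% in both. Cover was higher by over 20 points in 56 of the 181 genes and lower by over 20 points in 0. The 111 lower genes differed by 5.50 points and the other 6160 by 3.22. The difference of the higher genes exceeded all random sets matched on expression (percentile 100, range of 95% of sets 0.983 to 5.93), but sets matched on cover in control gained 11.001 points on average (95% of sets 7.61 to 14.5). Part of the 20.4 points was therefore shared with genes of the same starting cover.

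Genes with a region in 1 condition only were few. H3K36me3 was found after AngII only at 300 expressed genes, of which 33 were at least 2-fold higher and 10 lower, with a median log2 ratio of -0.16 (percentile 99.98 of matched sets). At the 127 genes with H3K36me3 in control only, 2 were higher and 10 lower (median -0.25, percentile 40.1). For H3K4me3, 105 genes had a region after AngII only (median -0.12, percentile 98.6) and 82 in control only (median -0.27, percentile 23.4). Over loci with coordinates of their own the percentile of the H3K4me3 genes after AngII only was 87.0.

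Loci without a gene name often carried both marks. Of 4951 expressed loci without an accession, 2019 (40.8%, 39.4 to 42.2) had H3K4me3 and H3K36me3 in at least 1 condition, against 9.02% after shifting the loci along their chromosomes. The shift shows only that these loci do not lie at random along the chromosomes. Marks counted at them can belong to a named neighbour, as H3K4me3 was taken within 1 kb of a locus. Pieces listed at the same interval share their marks: counted by interval, 1589 of 4481 (35.5%, 34.1 to 36.9) had both, against 5.86% after shifting. Of the 2019 loci, 143 were at least 2-fold higher after AngII (86 with bounds apart) and 247 lower (146 with bounds apart). Those with bounds apart lie at 51 and 85 distinct listed intervals, and a single interval on chromosome 5 supplies 58 of the 247 and 44 of the 146. The locus XLOC_029862 stood at 4.38 FPKM in control (3.08 to 5.69) and 31.9 FPKM after AngII (22.2 to 41.5), a log2 ratio of 2.61. It is 1 of 3 pieces listed at an interval on chromosome X (14911144 to 14928968), 6.09 kb from the microRNA gene Mir222. That interval had both marks in both conditions. The other 4 with the largest increase were XLOC_022935 (4.13), 0.162 kb from Ugcg, XLOC_003292 (3.19), 2.94 kb from P2ry6, and XLOC_008112 and XLOC_003431, which were listed at 0 in control and at 6.66 and 6.17 FPKM after AngII. Those with the largest decrease, XLOC_026219, XLOC_011288 and XLOC_023019, were listed at 0 after AngII and at 14.7, 14.6 and 8.27 FPKM in control. XLOC_022935, XLOC_003292, XLOC_003431, XLOC_026219 and XLOC_011288 span 154 to 245 bp, so their FPKM values are uncertain. XLOC_023019 is 1 of 58 pieces listed at the same interval of chromosome 5 (94391534 to 94622770), all of them lower after AngII with a median log2 ratio of -1.96.

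**Figure D4:**
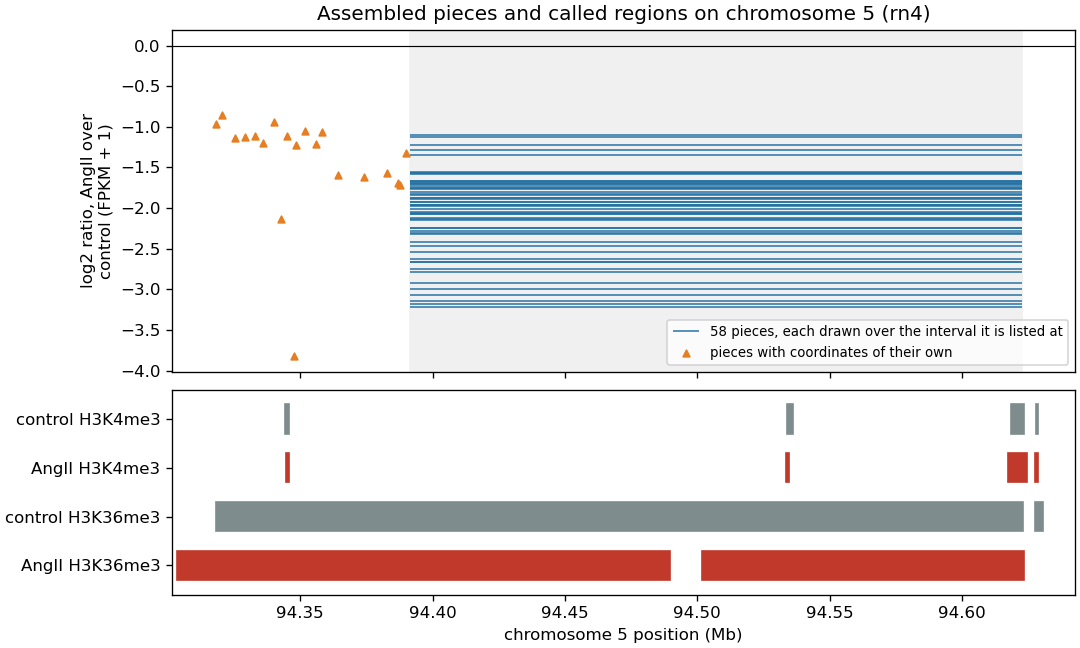
Log2 ratio of AngII over control on FPKM + 1 (y axis, top) against position on chromosome 5 in Mb (x axis), with the 58 pieces as blue lines over the interval they share in the listing, neighbouring pieces with coordinates of their own as orange triangles, and called regions of each mark in control (grey) and AngII (red) below. The median log2 ratio of the 58 pieces is -1.96, and H3K36me3 covers 100% of the interval in control and 94.8% after AngII.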

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

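The settings were chosen before the data were examined, except loci with coordinates of their own, loci over 300 bp, unnamed loci away from loci with an accession and unnamed loci counted by interval, which were chosen after seeing the data. The balance of higher and lower loci depended on the setting. Higher loci made up 45.5% of the calls as reported, 66.6% when centred, 72.1% with a pseudocount of 5 and 56.2% with FPKM minimum 5. The share was 52.1% scaled to the upper quartile, 49.7% with bounds that do not overlap and 44.1% for loci over 300 bp. It was 32.3% with a pseudocount of 0.1 and 31.4% with a threshold of 1.5-fold. Among the fixed lists, no median called apart from random lists reversed. The contractile, housekeeping and named long non-coding RNA medians went from below 0 to 0.18, 0.09 and 0.02 when centred. The 5 lists added after seeing the data were not recomputed under these settings. Of the comparisons that answer the design, 78 recomputed values stayed within their spread, or within 1.5 times for counts, and 36 moved; of 77 named genes, 223 values stayed and 8 moved, all 8 with a pseudocount of 0.1. No paired analysis was possible because each group holds 1 library, and no library could be left out for the same reason. Absolute sequencing depth is not given in the sources used here, and bounds of about 2.46-fold limit what these libraries can separate.

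Against 772 higher and 923 lower loci, a pseudocount of 0.1 gave 1272 and 2667, and a pseudocount of 5 gave 313 and 121, since the pseudocount sets how far weakly expressed loci count. Centring on the median ratio gave 1201 and 602. Fewer or more loci by construction were counted with FPKM minimum 5 (458 and 357), bounds that do not overlap (506 and 512) and a threshold of 1.5-fold (1663 and 3641). Leaving out the FPKM minimum left these counts at 772 and 923, as a 2-fold ratio on this scale needs an FPKM of 1. It took the list medians of the extracellular matrix genes to 0.02 (percentile 92.5, no longer apart from random lists), the angiotensin genes to 0.06 and the inflammatory genes to 0.33. With a pseudocount of 0.1 the cell cycle genes stood at percentile 2.6. The cell cycle median was -0.17 when centred, because the factor raises each AngII value.

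Among regions at or above the median score, overlap was 97.8% of control and 97.8% of AngII H3K4me3 regions, and 84.0% and 81.9% of H3K36me3 regions; Jaccard indices were 0.754 and 0.693, and the cause was not tested. Requiring 50% of the region gave 84.5% and 84.2% for H3K4me3 and 71.0% and 69.9% for H3K36me3, a stricter rule by construction.

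For expressed genes with H3K4me3, in control and AngII, a window of 5 kb gave 92.5% and 93.5%, FPKM minimum 5 gave 94.8% and 94.9%, and loci with coordinates of their own gave 88.0% and 89.6%. For H3K36me3, 50% of the locus gave 80.6% and 85.1%, FPKM minimum 5 gave 96.0% and 96.6%, and loci with coordinates of their own gave 91.9% and 93.8%. The cause of the FPKM and coordinate differences was not tested. Without the FPKM minimum 3249 unnamed loci carried both marks, by construction more than 2019. No unnamed locus overlapped a locus with an accession, so that setting moved nothing.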

Other observations

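The tests on the shift of the median locus, on the chromosome 5 unit and on region calling were chosen only after the result was seen; the gene lists here were added after the leading genes had been seen, without those genes, and before their own values were seen. Members named here were chosen after their values were seen.

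The list of MAP kinase feedback regulators, which also holds genes with other roles such as the interleukin receptor Il1rl1, had a median log2 ratio of 1.33 at percentile 100 of matched random lists, with 7 of 11 expressed members at least 2-fold higher and 0 lower. Il1rl1 (2.52), Errfi1 (2.45) and Phlda1 (2.22) led. FoxO-associated genes had a median of -0.65 at percentile 0.01, with 5 of 14 at least 2-fold lower, among them Txnip (-1.47), Klhl24 (-1.29) and Ccng2 (-1.26); Zfp36l2 (2.02) went the other way. This is consistent with a shared lower expression of FoxO-associated genes as a hypothesis, and FoxO activity itself was not measured.

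Circadian clock genes had a median of 0.23 at percentile 99.6, with Bhlhe40 (1.68) and Bmal1 (1.33) the 2 of 11 at least 2-fold higher and Per3 at -0.73. BMP pathway target genes had a median of -0.51 at percentile 1.64, with Smad6 (-1.43), Smad9 (-1.42) and Nog (-1.01) lower and Grem1 (2.30) higher. The members were divided: 7 of 12 lay below 0 and 5 above. Their mean log2 ratio was -0.21, against -0.14 over all expressed symbols. Vasoactive G-protein-coupled receptors were expected to be lower, as Agtr1a and P2ry6 were, but had a median of 0.24 at percentile 99.71; S1pr1 (2.38) and F2rl1 (1.13) were higher with bounds apart and 0 of 11 were 2-fold lower. The lower level of Agtr1a therefore did not extend to this list.

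The median expressed locus was lower after AngII. A uniform scaling difference as the whole cause is argued against by expression: the median log2 ratio was -0.33 (-0.36 to -0.30) at mean FPKM 1 to 4 and -0.14 (-0.16 to -0.13) at 15 and above, a difference of -0.19. The FPKM worth of 1 fragment, 1.01 times as large in control, argues against unequal normalising totals. It cannot show how the fragments were shared between a few abundant RNAs and the other loci. Pieces of assembled loci without an accession cannot be the whole cause, since loci with exactly 1 symbol had a median of -0.22. A response to AngII, a scaling difference as part of the cause and a difference in library composition stay open. The unstated starvation of control cells and variation between cultures also stay open, with 1 library per condition.

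Gain of H3K36me3 cover at genes higher after AngII may reflect co-transcriptional marking within 3 h, which is a hypothesis. The gain stood at percentile 100 of expression-matched sets, but those sets cannot decide this. Other expressed genes had a mean cover of 87.1% in control against 64.1% for the higher genes, which left them less room to gain. Lower starting cover does not account for all of the gain, since sets matched on control cover gained 11.001 points (7.61 to 14.5) against 20.4. It could account for part of the gain. More permissive region calls after AngII as the whole cause are argued against by other genes matched on control cover, control FPKM and locus length, which gained 10.8 points (7.57 to 14.01) against 20.03 for the 180 higher genes with a match. Such calls could still contribute, as the share of loci at FPKM 0 with H3K36me3 was 12.1% in control and 16.1% after AngII. Cover records whether a region was called, not how strong the mark is, and culture variation stays open.

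Among 30 units of 8 or more unnamed pieces listed at the same interval, the lowest lay on chromosome 5 (94391534 to 94622770). All of its 58 pieces were lower after AngII, with a median of 5.34 FPKM in control and 0.553 FPKM after AngII and a median log2 ratio of -1.96. The percentile was 0 among the lowest of 30 random units of separately drawn pieces in each of 10000 draws, whose minimum was -1.20. Pieces at 1 interval can move together: all 31 pieces of a chromosome 16 unit were lower and all 37 of a chromosome 7 unit higher. The draws therefore cannot tell whether the whole unit varied between cultures, which stays open with 1 library per condition. Whether the unit lost H3K36me3 stays open: cover was 94.8% of the control value but records calls only, and by score the control region stood at percentile 49.5 of its list against 20.8 and 18.4 for the AngII regions. The adjoining control H3K36me3 region of 252 kb (94045283 to 94297374) was overlapped near its end by an AngII region of 3.29 kb. Regions were listed only near the unit, so cover after AngII over the rest of the 252 kb was not tested. Weakly expressed unnamed pieces within this control region were also lower (-0.87 to -0.41).

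A unit of 37 pieces on chromosome 7 (65316392 to 65370150), 2.82 kb from Slc16a7, was higher in all 37 pieces, with a median log2 ratio of 1.34 and H3K36me3 cover of 0% in control and 64.2% after AngII. The highest unit, 13 pieces on chromosome 3 (86137577 to 86188537), had a median log2 ratio of 1.43 and a median FPKM listed at 0 in control and 1.69 after AngII, with neither mark in either condition.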
